A study of Mus musculus with 12 samples.

How the data were processed

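Gene expression was measured in 12 spleen RNA samples on 2-colour Agilent oligonucleotide arrays, 1 sample per array. The samples came from 564 Igi mice at 4 months (n = 3), 8 months (n = 3) and 12 months (n = 4) and from C57BL/6 mice at 4 months (n = 2), and all are described as female. Per the labels, the spleen RNA was labelled with Cy3 and a universal reference RNA with Cy5 on every array, so dyes were not swapped and a dye effect of an oligo is shared by all arrays. Nothing states that each sample came from a separate animal, so p-values measure the spread between these samples. The sample descriptions give the knock-in genotype as 564+/-, whereas the treatment text says that homozygous 564+/+ animals served throughout, and the data given here do not settle which applies. The same text says that some of the homozygous colony received antibiotics in its drinking water, and it does not say whether these samples came from there.

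Per the file headers, the arrays were quantified with Agilent Feature Extraction 11.5.1.1, which removed the local background, corrected spatial trends and normalized the dyes by lowess with a smooth factor of 0.25. The intensity columns hold, per the file headers, the mean brightness of each spot and its median local background on the scanner's linear scale, without normalization, and a second pair of intensity columns holds the processed signals. The log ratio of each spot was deposited as log10 of reference over sample, and here its sign was turned. The deposited series table holds the same log10 values rounded, with a largest difference of 0.005 on each array, medians of 0 on 11 arrays and 0.00197 on 564 Igi 4 months replicate 1, and 4.17% to 12.0% of spots at exactly 0. Its scale and direction were therefore known, and no gene was centred. Other deposited columns are flags for spots well above background, saturated spots and spots of uneven signal or background. The authors' choice of statistical test is not given in the sources used here.

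Mean signals and median backgrounds were read with limma 3.58.1 in R 4.3.3. The background was corrected by normexp with an offset of 50, fitted on all spots, and each array was normalized by loess with control spots at weight 0. Values are log2 of sample over reference. On 564 Igi 8 months replicate 2, 4 months replicate 1 and 4 months replicate 3, spots with an uneven local background distorted the normexp fit, which put the 1st percentile of corrected Cy3 signal at 375, 761 and 248. Such spots were therefore given the median background of their array for the fit and then left out, after which the same percentile was 58.5, 61.6 and 58.8. This repair was chosen after the data and the numbers of changed oligos had been seen, and the fit as first planned is among the alternatives. From 17 to 80 oligo spots per array were left out as uneven. No Cy3 spot and 5 Cy5 spots were saturated, and they were kept. An oligo was kept if it was well above background in the Cy3 channel on all arrays of at least 1 group, which 26291 of 35856 oligos were. Of these, 26280 had a value in every group and were tested, 280 of them with at least 1 array missing.

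Of the oligos, 34819 have 60 bases and 1037 have 50. The files give an identifier and a sequence for each oligo and do not pair them with genes, and the table of mouse genes at hand (assembly GRCm38.p6) shares no key with the identifiers. The planned gene lists for blood cell types, interferon response and proliferation, the naming of genes by symbol, the choice among probes of a gene and the check of sex-specific genes were therefore not done. Each oligo counts as 1 feature. In place of the lists, oligo sequences were translated in the 3 forward frames with Biopython 1.88 and searched for conserved protein patterns of antibody light-chain variable (V) regions, heavy-chain or T cell receptor V regions, C2H2 zinc fingers, collagen-like repeats and olfactory receptors. These 5 classes were chosen after the changed oligos had been seen, so a change in a class is not independent evidence. The patterns found 46, 16, 29, 10 and 9 oligos. On the reverse strand they found 5, 0, 0, 3 and 0, which shows how many hits arise by chance, and they miss oligos whose sequence lies outside the conserved stretches and some that lie inside them. The light-chain patterns can also match T cell receptor segments. By identifier, only the 2 oligos with the largest rise and the 2 with the largest fall per comparison are named, among oligos past the threshold whose arrays do not overlap between the groups. Where fewer than 6 passed, those with the smallest p are given as values that did not pass, except 1 that did. This rule on identifiers was also set after the values had been seen.

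All 12 arrays entered 1 limma fit (lmFit and eBayes) with a coefficient per group, 8 residual degrees of freedom and a prior of 3.71. Oligos with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The 6 comparisons were 564 Igi at each age against C57BL/6, each pair of ages within 564 Igi, and a moderated F test over the 3 ages. Classes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 5 classes within a comparison, and enrichment among called oligos was tested with Fisher's exact test adjusted over all 30 class and comparison pairs. All camera and fry tests are two-sided. For an oligo not well above background on any array of the lower group, the fold is a bound. It sets the mean of the brighter group against the mean of, per array, the higher of the oligo's own signal and the lowest signal among oligos well above background, after loess and Aquantile scaling of the Cy3 channel, and it stays open to dye bias.

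The fit was tested on simulated data drawn from the 26280 oligos, of which 67, 67 and 66 were changed 2-, 4- and 8-fold. For 564 Igi against C57BL/6 at 4 months it recovered 83.6% of 2-fold, 97.0% of 4-fold and 98.5% of 8-fold changes. For 8 against 4 months it recovered 92.5%, 100% and 98.5%. For 12 against 4 months and for 12 against 8 months it recovered 92.5%, 100% and 100%. Against C57BL/6 it recovered 89.6%, 100% and 100% at 8 months and 91.0%, 100% and 100% at 12 months. Between 7 and 15 of 26080 unchanged oligos were called. The simulation holds no slide effect and draws independent normal noise. Its planted changes also ease the adjusted threshold, which is stricter where few oligos change. Recovery in the comparisons of ages may therefore be lower, and counts of 0 there do not exclude 2-fold changes. In the data, M400006787 differed 2.84-fold between 12 and 4 months and did not pass (limma, adjusted p = 0.0742).

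The groups, tests, filter and most alternatives were fixed before the data were examined. The alternatives covered the background correction, the normalization, the sample channel alone, the filter, the slide and the replicate number as blocks, array weights, the variance prior, the arrays in the fit and leaving out each array in turn. The 12 arrays lie on 3 slides of 4, and each slide was scanned together, so slide and scan are 1 batch. A further 42 features with other forms of name, on 168 spots, were left out of the tests. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.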

Results

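Spleen expression was profiled in 564 Igi mice, a knock-in strain that carries the rearranged heavy and light chain genes of an autoantibody at its own antibody loci, and in C57BL/6 mice, the strain background. The 564 Igi samples were taken at 4 months (n = 3), 8 months (n = 3) and 12 months (n = 4), and the C57BL/6 samples at 4 months (n = 2). Each array compared spleen RNA with a universal reference RNA over 35856 oligos of 50 or 60 bases. The files do not pair the oligos with genes, so single oligos are given by identifier and groups of oligos by the protein pattern that their sequence encodes. The Cy3 channel, which held the spleen RNA, was well above background at 69.5% to 75.9% of the oligos on 11 arrays and at 91.2% on 564 Igi 4 months replicate 1. The median Cy3 signal per array lay between 102 and 149. Slide 1 held 4 of the 564 Igi arrays and no C57BL/6 array, and slides 2 and 3 each held 1 C57BL/6 array beside 3 of the 564 Igi arrays. The precision of every value is limited by the number of arrays.

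Pairs of arrays within a group correlated at r = 0.938 to 0.969 across oligos, which are not independent replicates. C57BL/6 arrays correlated with 564 Igi arrays at a median r of 0.923, and 564 Igi arrays of different ages with each other at a median r of 0.956. The first principal component, with 27.0% of the variance, placed the C57BL/6 arrays at 39.5 and 37.6 and the 564 Igi arrays between -21.0 and 6.52. The second component, with 17.4%, placed 564 Igi 12 months replicate 4 at 40.1 and all others between -20.4 and 11.1. Oligos with a run of at least 9 bases of the telomere-like repeat CCCTAA (30 oligos) also differed between arrays. Their median deviation from the 12-array mean was 1.20 on 564 Igi 12 months replicate 4, 1.04 and 0.73 on the C57BL/6 arrays, 0.51 on 564 Igi 8 months replicate 3, and between -0.58 and -0.19 on the other 8 arrays, on the log2 scale.

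**Figure D1:**
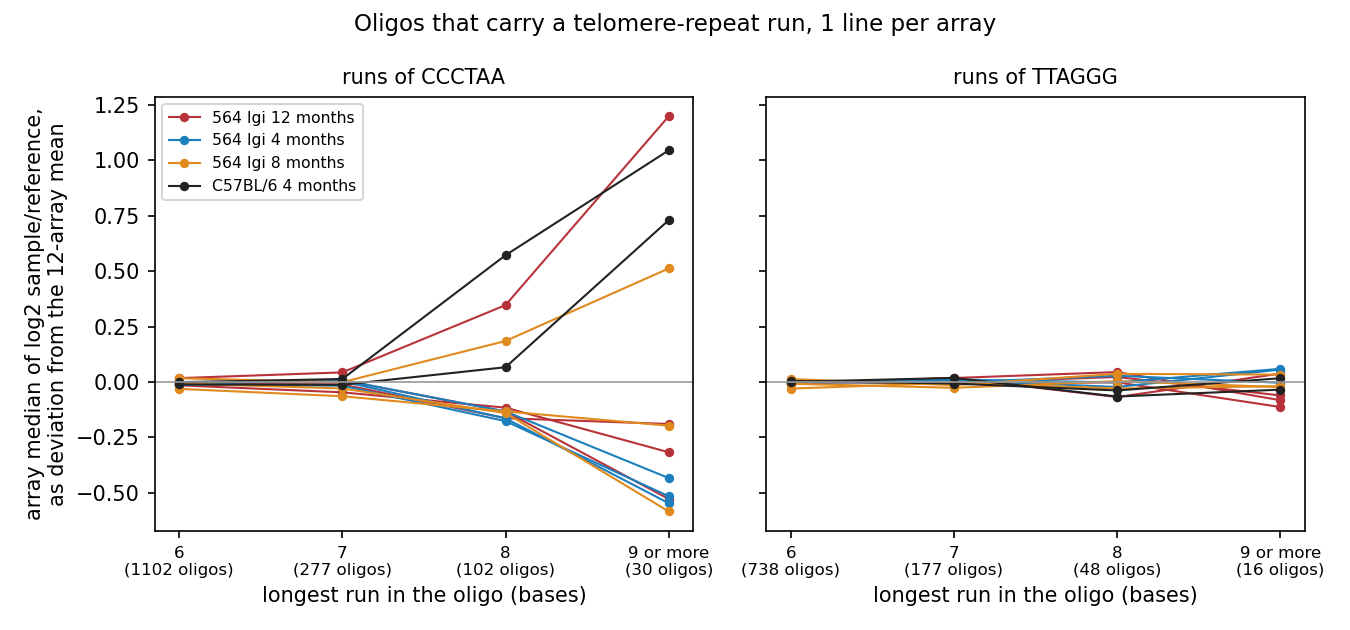
Array medians of log2 sample over reference, as deviation from the 12-array mean, against the longest run of the repeat in the oligo in bases, with 1 line per array coloured by group, for runs of CCCTAA (left) and TTAGGG (right). At runs of 9 or more bases of CCCTAA, 4 arrays lie between 0.51 and 1.20 and 8 between -0.58 and -0.19, whereas the lines for TTAGGG stay near 0.

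The comparison of 564 Igi with C57BL/6 at 4 months asks what the knock-in changed in the spleen at the only age at which both strains were measured. In 564 Igi, 18 of 26280 oligos were higher and 89 were lower (limma, adjusted p under 0.05). Oligos that encode light-chain V patterns were prominent among them, with 29 of the 89 that fell, at a median of 8.19-fold, and 4 of the 18 that rose, at a median of 4.89-fold. Light-chain V regions form part of the antigen-binding site of antibodies. The 60 other oligos that fell did so by a median of 1.93-fold, and the 14 others that rose by a median of 3.01-fold. The patterns miss some V-region oligos, and these others include M400010435, M400008025 and M400007654, which share sequence with light-chain V oligos of the class. Of the 89, 7 were not well above background on any 564 Igi array at 4 months, so the medians of the falls rest in part on fitted values. No oligo of the heavy-chain or T cell receptor V class was called in either direction.

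The largest falls were in M400005124 and M400010435. M400005124 (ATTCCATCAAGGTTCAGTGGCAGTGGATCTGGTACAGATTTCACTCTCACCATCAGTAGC), which encodes a light-chain V framework 3 pattern, had a log2 ratio to the reference of 2.15 ± 0.50 (SD, n = 2) in C57BL/6 and -3.82 ± 0.12 (n = 3) in 564 Igi. Its log2 fold change was -5.97 (SE 0.26, 62.9-fold lower, adjusted p = 1.77e-07). M400010435 (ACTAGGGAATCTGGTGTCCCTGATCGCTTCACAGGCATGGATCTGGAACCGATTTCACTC), which matched no pattern searched, changed by -5.30 (SE 0.24, 39.5-fold lower, adjusted p = 2.55e-07), from 0.35 ± 0.08 (n = 2) to -4.95 ± 0.24 (n = 3). The largest rises were in M400008025 and M400007654, which also matched no pattern. M400008025 (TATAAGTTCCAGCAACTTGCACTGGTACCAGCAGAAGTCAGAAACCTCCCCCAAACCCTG) went from 2.50 ± 0.56 (n = 2) to 5.55 ± 0.37 (n = 3), a log2 fold change of 3.05 (SE 0.36, 8.26-fold, adjusted p = 0.00126). M400007654 (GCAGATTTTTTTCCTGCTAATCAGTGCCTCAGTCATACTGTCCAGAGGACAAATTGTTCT) went from 2.10 ± 0.46 (n = 2) to 5.12 ± 0.27 (n = 3), a log2 fold change of 3.02 (SE 0.29, 8.14-fold, adjusted p = 1.86e-04). On slide 2, which held 1 array of each group, the differences were -5.65, -5.00, 3.83 and 3.65 in the order given here.

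Of the 44 light-chain V oligos detected, 29 fell, 4 rose and 11 did not pass. With uneven-background spots kept, as first planned, 27 fell and 0 rose, and with the scanner's processed ratios 22 fell and 1 rose. With the sample channel alone 31 fell and 4 rose, and with median centring 28 fell and 5 rose. The class median log2 fold change was -2.00 (quartiles -3.26 and -0.30), and 35 of the 44 lay below 0. The class was shifted down against the other oligos (camera adjusted p = 1.68e-52 with the preset correlation, adjusted p = 0.00332 with an estimated correlation). Called oligos made up 75% of the class and 0.282% of the other 26236 oligos (Fisher's exact test, adjusted p = 1.20e-70). The class was chosen after these called oligos had been seen, and Fisher's test takes oligos that share sequence as independent. Its p is therefore no evidence beyond the calls themselves. All 4 framework 3 oligos fell, as did 10 of 13 at the end of framework 3, 4 of 6 with the J segment pattern, which T cell receptor J segments can also match, and 7 of 10 at the start of framework 1. Of the 6, M400009410 (log2 fold change -0.31), which did not pass, reads as a T cell receptor J segment and not a light-chain one. Framework 2 held 3 of the 4 that rose, with 4 that fell and a median of -0.09 over its 11 oligos. That median is the value of M200000771, which may be a chance match to the pattern. M200011670 (log2 fold change 0.11), also counted in framework 2, translates with stop codons and is a likely chance match. Such matches are counted among the oligos of the class that did not pass. Every 564 Igi array had a class median between -2.10 and -1.65 relative to the C57BL/6 mean, and the C57BL/6 arrays lay at -0.30 and 0.30. On slide 2 the class median differed by -1.80. With only the 21 members well above background in both channels on all arrays, the class median was -0.30. That filter requires signal on every 564 Igi array, so it can drop members because they fell, as it drops M400010429 (log2 fold change -5.01). The smaller median may follow in part from that selection.

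The 16 detected heavy-chain or T cell receptor V oligos had a median log2 fold change of 0.77, with 14 above 0 and none called. The preset camera test passed (adjusted p = 1.84e-04), and the test with an estimated correlation did not (adjusted p = 0.408), nor did fry (p = 0.106 before adjustment over the classes). The 29 C2H2 zinc finger oligos had a median of 0.13 (adjusted p = 0.0762), which was -0.16 with the sample channel alone and above 0 under the other background and scaling settings. The 7 collagen-like and 3 olfactory receptor-type oligos had medians of -0.10 and -0.04 (adjusted p = 0.382 for both). The 132 oligos with a telomere-like run of at least 8 bases had a median of -0.54, with 108 of them lower and 0 called.

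The groups did not overlap for any of the called oligos, and over all complete oligos 34.7% did not overlap, where chance gives 20%. The number called was 112 (8 higher, 104 lower) with uneven-background spots kept, 54 with the filter on both channels, 67 with the scanner's own processed ratios, 197 with only the arrays of these groups in the fit, 71, 69 and 70 without 564 Igi 4 months replicate 1, 2 and 3, and 206 without 564 Igi 12 months replicate 4. With each array left out in turn, the number higher ranged from 5 (without C57BL/6 replicate 1) to 30 (without 564 Igi 12 months replicate 4) and was 10, 11 and 9 without 564 Igi 4 months replicate 1, 2 and 3. When uneven-background spots entered the background fit, neither M400008025 (log2 fold change 2.43, adjusted p = 0.137) nor M400007654 (log2 fold change 2.22, adjusted p = 0.145) passed, and M400007654 did not pass with the processed ratios (log2 fold change 0.70, adjusted p = 0.441).

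**Figure D2:**
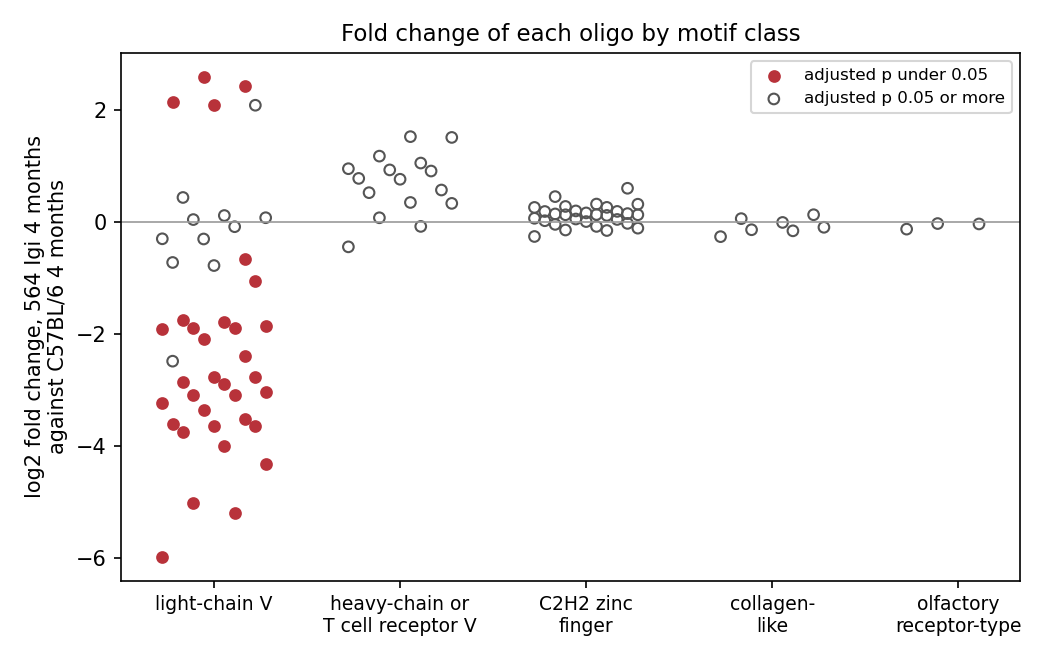
Log2 fold change of each detected oligo in 564 Igi against C57BL/6 at 4 months (vertical axis) by the protein pattern its sequence encodes (horizontal axis), with filled points for adjusted p under 0.05. Of the 44 light-chain V oligos, 29 filled points lie below 0 and 4 above, and the other 4 classes hold no filled point.

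The comparison of 8 with 4 months asks how expression changed with age within 564 Igi. No oligo passed the threshold in limma. An unadjusted p under 0.05 was found for 826, below the share of 0.05 that chance gives. The light-chain V class had a median log2 fold change of -0.0035 over 44 oligos (adjusted p = 0.967), with 22 above 0, 22 below 0 and none called. The heavy-chain or T cell receptor V class had a median of 0.13 (adjusted p = 0.367), but its median difference was 0.79 within slide 1 and -0.79 within slide 2. The C2H2 zinc finger class had a median of -0.11, with 27 of 29 oligos below 0, and passed with the preset correlation (adjusted p = 0.00449) but not with an estimated correlation (adjusted p = 0.580).

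The smallest p in each direction belonged to M200006691, at 0.86 (SE 0.14), and M400009230, at -0.53 (SE 0.12), on the log2 scale, both with an adjusted p of 1.00 after rounding. The log2 ratio of M200006691 was -0.72 ± 0.08 (n = 3) at 4 months and 0.14 ± 0.27 (n = 3) at 8 months, and its difference was 1.12 on slide 1 and 0.77 on slide 2. The arrays of the groups did not overlap for 9.20% of oligos, where chance gives 10%.

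The comparison of 12 with 4 months spans the widest range of age in 564 Igi. A single oligo passed, M400006858 (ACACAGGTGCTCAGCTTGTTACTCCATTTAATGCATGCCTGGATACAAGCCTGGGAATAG), which rose from -0.06 ± 0.35 (n = 3) at 4 months to 1.59 ± 0.23 (n = 4) at 12 months, a log2 fold change of 1.65 (SE 0.18, 3.14-fold, adjusted p = 0.0282). Its level was 0.04 ± 0.24 (n = 3) at 8 months and -0.29 ± 0.21 (n = 2) in C57BL/6. The light-chain V class had a median of 0.05 and the heavy-chain or T cell receptor V class a median of 0.27 (adjusted p = 0.241 for both), with none of their oligos called. The C2H2 zinc finger class had a median of -0.14, with 28 of 29 oligos below 0, and passed with the preset correlation (adjusted p = 2.50e-04) but not with an estimated correlation (adjusted p = 0.635).

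The 12-month arrays differed among themselves in the zinc finger class, from -0.38 on replicate 4 to 0.26 on replicate 3 relative to the C57BL/6 mean. The collagen-like class had a median of 0.19 (adjusted p = 0.0540). The next smallest p among rises was that of M400006787, at 1.51 (SE 0.20, adjusted p = 0.0742), and the smallest among falls that of M400009253, at -1.30 (SE 0.18, adjusted p = 0.0742). The groups did not overlap for 8.80% of oligos, where chance gives 5.71%. The difference in M400006858 was 1.51 on slide 1 and 1.30 on slide 2. Its call was lost with slide as a block (adjusted p = 0.106), with the replicate number as a block (adjusted p = 0.171) and under 13 of 29 alternatives in all, and over all 29 its adjusted p ranged from 0.00542 to 0.323 and its log2 fold change from 1.53 to 2.72. The number called went from 0 to 15 over the alternatives, with 8, 5 and 3 without 564 Igi 8 months replicate 1, 8 months replicate 2 and 4 months replicate 3, and 0 without 8 months replicate 3, 4 months replicates 1 and 2, either C57BL/6 array or 12 months replicates 2, 3 and 4.

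Between 12 and 8 months, no oligo passed the threshold in limma. An unadjusted p under 0.05 was found for 1110, below the share of 0.05 that chance gives. M400006858 had the smallest p, with a log2 fold change of 1.55 (SE 0.18, adjusted p = 0.0539), and differences of 0.94, 1.70 and 1.87 on slides 1, 2 and 3. It passed under 8 of 29 alternatives, over which its adjusted p ranged from 0.00905 to 1.00. M200000089 had the smallest p among falls, at -3.15 (SE 0.61, adjusted p = 0.990). The light-chain V, heavy-chain or T cell receptor V and C2H2 zinc finger classes had medians of 0.05, 0.04 and -0.03 (adjusted p = 0.328, 0.958 and 0.328). Within slides 1, 2 and 3 the heavy-chain or T cell receptor V class differed by -0.96, 1.04 and -0.05, so its direction changed with the slide. The groups did not overlap for 4.62% of oligos, where chance gives 5.71%.

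Over the 3 ages of 564 Igi together, the moderated F test called M400006858 (adjusted p = 0.0275) and no other oligo. An unadjusted p under 0.05 was found for 1286, slightly below the share of 0.05 that chance gives. The next smallest adjusted p was 0.179, for M400006787, whose means were 1.52, 1.84 and 3.03 at 4, 8 and 12 months. The count was 0 with slide or replicate number as a block, with the processed ratios and with median centring. It was 2 without 8 months replicate 1, 8 months replicate 2 or 4 months replicate 3, and 0 without 8 months replicate 3, 4 months replicate 1 or 2, either C57BL/6 array or 12 months replicate 2, 3 or 4.

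The remaining comparisons set the older 564 Igi groups against C57BL/6 at 4 months, so genotype and age are mixed in them. At 8 months, 34 oligos were higher and 130 lower in 564 Igi. Light-chain V oligos made up 30 of those that fell, at a median of 7.63-fold, and 5 of those that rose, at a median of 6.08-fold (28 and 0 with uneven-background spots kept, 23 and 1 with the processed ratios), and 21 of the 130 were not well above background on any 564 Igi array at 8 months. M400005124 and M400010435 were lower, with log2 fold changes of -5.91 (SE 0.26, adjusted p = 1.99e-07) and -5.35 (SE 0.24, adjusted p = 2.48e-07). M400007654 and M400008025 were higher, with 3.46 (SE 0.29, adjusted p = 4.90e-05) and 3.33 (SE 0.36, adjusted p = 5.16e-04).

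The light-chain V class median was -2.11, with 37 of 44 oligos lower (camera adjusted p = 0.00416 with an estimated correlation). It was -1.90 within slide 2 and -2.42 within slide 3. With only the 21 members well above background in both channels on all arrays it was -0.27, a filter that can drop members because they fell. Called oligos made up 79.5% of the class against 0.492% of the others (Fisher's exact test, adjusted p = 1.42e-69), with the same limit on this p as at 4 months. The heavy-chain or T cell receptor V class had a median of 0.88 (preset adjusted p = 1.02e-05), with an adjusted p = 0.280 with an estimated correlation and no oligo called. Its fry p was 0.0586 before adjustment over the classes. With an offset of 16 or with the processed ratios, 1 oligo of this class was called higher. The telomere-like oligos had a median of -0.51, with 111 of 132 lower and 0 called. The groups did not overlap for 28.8% of oligos, where chance gives 20%. The number called was 577 (335 higher, 242 lower) without 8 months replicate 2, 101 without 8 months replicate 1, 101 without 8 months replicate 3 and 252 without 12 months replicate 4, and with median centring it was 104 (43 higher, 61 lower). The number higher was 7 and 18 without C57BL/6 replicate 1 and 2, and 20 without 8 months replicate 1 or replicate 3. With uneven-background spots kept, it was 98 (6 higher, 92 lower) and M400008025 and M400007654 did not pass (log2 fold changes 2.82 and 2.78, adjusted p = 0.125 and 0.109), and M400007654 did not pass with the processed ratios (log2 fold change 0.91, adjusted p = 0.232).

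At 12 months, 84 oligos were higher and 154 lower than in C57BL/6 at 4 months. Light-chain V oligos made up 30 of those that fell, at a median of 7.83-fold, and 5 of those that rose, at a median of 6.87-fold (29 and 2 with uneven-background spots kept, 24 and 3 with the processed ratios). The 79 other oligos that rose did so by a median of 2.56-fold, and the 124 others that fell by a median of 1.96-fold, with 23 of the 154 not well above background on any array at 12 months. M400007654 and M400008025 were higher by 3.63 (SE 0.27, adjusted p = 1.66e-05) and 3.59 (SE 0.34, adjusted p = 1.50e-04), and M400005124 had a log2 fold change of -5.68 (SE 0.25, adjusted p = 1.59e-07). M400010429 (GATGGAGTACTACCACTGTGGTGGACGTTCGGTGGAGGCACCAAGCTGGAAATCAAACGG), which encodes a light-chain J segment, was not well above background on any of the 4 arrays at 12 months. Its Cy3 signal alone was at least 90.5-fold lower than in C57BL/6. Its log2 ratio to the reference differed by less, at -5.11 (SE 0.16, adjusted p = 7.26e-09), as its mean Cy5 signal before background correction was also lower, at 54.6 against 190.2 in C57BL/6.

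The light-chain V class median was -1.90, with 37 of 44 lower (camera adjusted p = 0.00327 with an estimated correlation). It was -1.71 within slide 2 and -2.22 within slide 3. With only the 21 members well above background in both channels it was -0.33, a filter that can drop members because they fell. Called oligos made up 79.5% of the class against 0.774% of the others (Fisher's exact test, adjusted p = 1.52e-63). The heavy-chain or T cell receptor V class had a median of 1.00, with 15 of 16 above 0 and none called (preset adjusted p = 1.66e-06, adjusted p = 0.226 with an estimated correlation). Its fry p was 0.0423 before adjustment over the classes, and fry for changes in either direction gave an adjusted p of 0.0247. With an offset of 16, the processed ratios or median centring, 1 oligo of this class was called higher. The telomere-like oligos had a median of -0.42, with 106 of 132 lower and 0 called. The groups did not overlap for 20.3% of oligos, where chance gives 13.3%. The number called was 127 (46 higher, 81 lower) with median centring and 109 (23 higher, 86 lower) with uneven-background spots kept, the number higher was 38 and 32 without C57BL/6 replicate 1 and 2, and M400007654 did not pass with the processed ratios (log2 fold change 0.71, adjusted p = 0.284). The 3 comparisons with C57BL/6 share its 2 arrays, so their resemblance comes in part from those arrays.

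**Figure D3:**
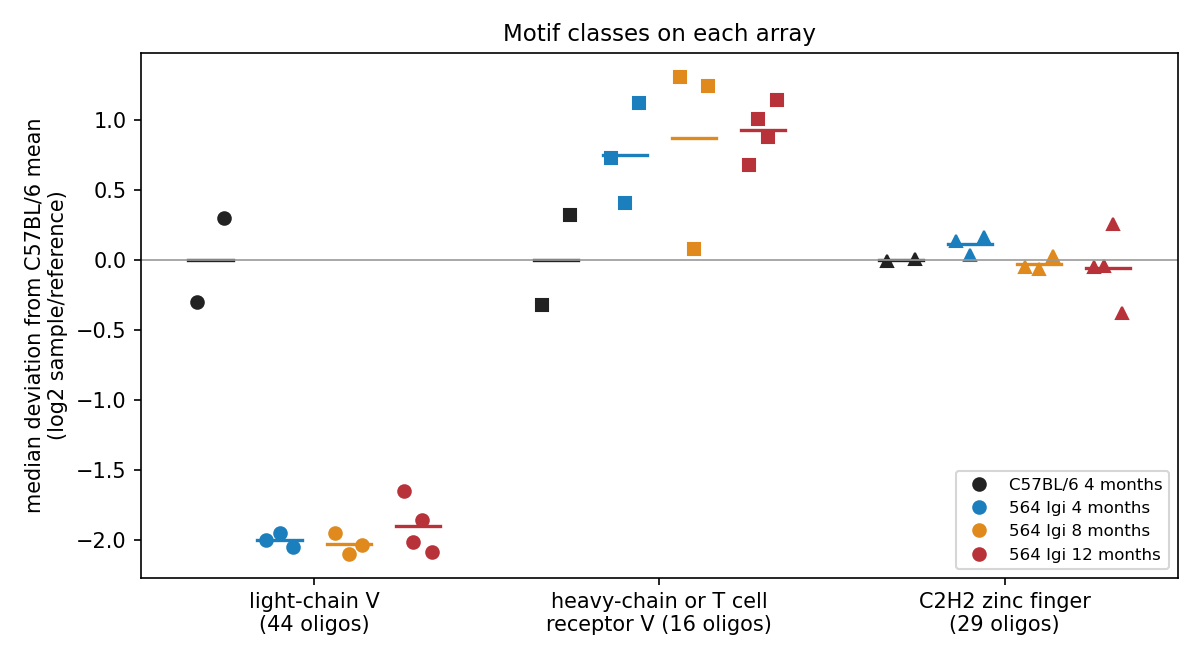
Median deviation of each class from the C57BL/6 mean, in log2 sample over reference, with 1 point per array coloured by group and a bar at the group mean. The light-chain V medians of the 10 arrays of 564 Igi lie between -2.10 and -1.65, and the heavy-chain or T cell receptor V medians between 0.08 and 1.31, with the C57BL/6 arrays at -0.32 and 0.32 in the latter.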

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

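The tests of the telomere-like oligos on the other strand and by run length were chosen only after the result had been seen, and the test of their range under other settings was fixed before it. Among the 4 arrays of 564 Igi at 12 months, 18 measures were checked for an array far from the other 3, and in 4 of them its gap to the nearest array exceeded Dixon's critical value for 4 values. Chance gives this in about 1 of 20 groups, and the measures are not independent. The share of oligos well above background in Cy3 was 75.9% on replicate 2 against 69.5% to 70.4% on the others (gap over range 0.852). In Cy5 it was 65.6% on replicate 1 against 71.8% to 72.5% (gap over range 0.897). The light-chain V oligo M400005124 had a log2 ratio of -4.01 on replicate 2 and between -3.40 and -3.29 on the others (gap over range 0.858), with the C57BL/6 arrays at 1.80 and 2.50.

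The oligos with a telomere-like run of at least 8 bases had a median deviation of 0.46 on 12 months replicate 4 and between -0.23 and -0.16 on the other 12-month arrays (gap over range 0.902). Over all 12 arrays their medians spanned 0.958 on the log2 scale, and they spanned at least 0.957 under every other background, scaling and channel setting tried, which argues against the background correction and normalization. The same run on the other strand spanned 0.0932, which argues against labelled genomic DNA, since that would bind both strands. With median centring the other strand spanned 0.572, so the contrast between strands was smaller under that setting. On 12 months replicate 4 the deviation was larger by 0.851 at runs of 9 or more bases than at runs of 8, and a labelled sequence that carries the repeat, such as a transcript, may therefore be the source; whether it is biological was not tested, and genotype, slide 3 and RNA handling stay open, since the raised arrays are both C57BL/6 arrays and 2 of the 564 Igi arrays of slide 3. Slide 3 alone does not account for them: at runs of 9 or more bases C57BL/6 replicate 1, on slide 2, lay at 1.04, and 12 months replicate 3, on slide 3, at -0.53.

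A signal also appeared on 42 features whose names have another form and that entered no comparison. Of their 168 spots, 39.3% were well above background in Cy3 on 564 Igi 4 months replicate 1, 8.93% on 4 months replicate 2, 10.1% on 4 months replicate 3, 8.33% on 8 months replicate 2 and 10.7% on 12 months replicate 2. The other 5 arrays of 564 Igi had 2.98% to 7.14% and the C57BL/6 arrays 7.14% and 5.95%, so the higher shares do not follow the strain. Negative control spots had at most 1.31% on any array. On 4 months replicate 1 the share among the ordinary oligos, 91.2%, was also the highest of the 12 arrays.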

How the results depend on the processing

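The repair of uneven-background spots in the fit reported, leaving out the arrays that stand apart and all settings for motif classes and single oligos were chosen after the data had been seen, and uneven-background spots kept is the fit as first planned. The 5 oligos run under the alternatives (M400008025, M400007654, M400005124, M400010435 and M400006858) and the light-chain V medians against C57BL/6 did not change direction, whereas several class medians near 0 did under other background, scaling or channel settings, and the balance at 8 months against C57BL/6 turned from 34 higher and 130 lower to 335 higher and 242 lower without 8 months replicate 2. At 4 months against C57BL/6, 18 higher and 89 lower oligos in the fit reported became 67 in all with the processed ratios, 67 with the deposited series table, 112 (8 higher, 104 lower) with uneven-background spots kept, 69 (20 higher, 49 lower) with median centring, 54 with the filter on both channels (20788 oligos tested), 197 with only the groups compared, 237 without 564 Igi 12 months replicate 4 and 8 months replicate 3, and 69 to 206 with each array left out in turn (71, 69 and 70 without 4 months replicates 1, 2 and 3, and 206 without 12 months replicate 4). At 8 months against C57BL/6, 164 became 85 with the processed ratios, 86 with the series table, 104 (43 higher, 61 lower) with median centring, 83 with the filter on both channels, 98 with uneven-background spots kept, 69 with only the groups compared, and 101 to 577 with each array left out (101, 577 and 101 without 8 months replicates 1, 2 and 3, and 252 without 12 months replicate 4). At 12 months against C57BL/6, 238 became 127 (46 higher, 81 lower) with median centring and 109 with uneven-background spots kept, and 159 to 284 with each array left out. The count for 8 against 4 months was 0 under all 29 alternatives. For 12 against 4 months, 1 became 3 with an offset of 16, 0 with the processed ratios or the series table, 3 with median centring, 2 with uneven-background spots kept, 0 with slide as a fixed block, 15 with array weights, 6 with only the groups compared, 0 without the 2 arrays that stand apart and 0 to 8 with each array left out (8 and 5 without 8 months replicates 1 and 2, 3 without 4 months replicate 3, 0 without 8 of the others). For 12 against 8 months, 0 became 1 with the sample channel alone, the filter on both channels, uneven-background spots kept, slide as a random block, trend and robust variance, or only the groups compared, and 0 to 2 with each array left out (2 without 8 months replicate 1 or 4 months replicate 3, 1 without 12 months replicate 1). Across the 3 ages, 1 became 0 with the processed ratios, the series table, median centring, slide as a fixed block, only the groups compared or without the 2 arrays, 2 with uneven-background spots kept, and 0 to 2 with each array left out (2 without 8 months replicates 1 or 2 or 4 months replicate 3). The cause of these moves was not tested.

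The light-chain V median at 4 months stayed between -3.35 and -0.30 over 32 alternatives, and was -1.80 within slide 2. In the fit reported, camera with an estimated correlation gave p = 6.64e-04 before adjustment. That p does not show how the class test holds under other processing, and the class was chosen after the calls had been seen. M400005124 and M400010435 passed at 4 months under all 29. Leaving out a C57BL/6 array leaves 1, which is assumed to vary like the other groups. Arrays with the same replicate number did not deviate together (r from -0.229 to 0.293 over 15 pairs, 5 above 0.1), and 4 of 12 arrays correlated best with their own number. The check thus gave no sign that the numbers pair the samples. It cannot exclude a pairing, since deviations from the mean of so few arrays are tied to each other within a group. Arrays on the same slide deviated together more often, with a median r of 0.126 and 9 of 16 pairs above 0.1, against a median r of -0.0867 and 9 of 37 pairs on different slides, and the fit reported leaves slide out. The replicate block gave 0 for 12 against 4 months and 0 across the ages, and moved no other count by over 1.5 times. The Aquantile step moved no ratio. The mean of all probes of a gene was not run, for want of gene names. Signal over background limits the bounds, since dim oligos give only a lower limit of the fold.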

Other observations

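The test by array scaling and the other splits of the arrays were fixed before their results had been seen, and the tests by slide, heavy-chain class and rising oligos only after. Oligo M200000089 lay at either of 2 levels, which split the arrays of 564 Igi at 4 months and not those of the other groups. Its log2 ratio was 2.24, 1.74 and 2.07 on the arrays of 564 Igi at 8 months, 2.43, 2.15 and -0.94 on replicates 1, 2 and 3 at 4 months, and between -1.44 and -0.76 on the 4 arrays at 12 months. Both C57BL/6 arrays lay at -1.25 and -1.23. It was chosen after its values had been seen, and no explanation was tested.

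The light-chain V oligos that fell at 4 months kept low values at every age: the array medians over those 29 lay between -3.14 and -2.83 relative to the C57BL/6 mean on all 10 arrays of 564 Igi, and those over the 4 that rose between 2.15 and 3.13. These oligos were picked at 4 months, so only the 8- and 12-month arrays add to that, and they share the same C57BL/6 arrays.

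The fall of the light-chain V oligos was weighed against 3 explanations other than the knock-in chain. Array scaling is argued against by a class median of -1.85 or lower under every other background, scaling and channel setting, and a difference between slides by -1.80 within slide 2. A lower share of B cells as the whole cause is argued against by the heavy-chain or T cell receptor V class, whose median was 0.77 and stayed between 0.40 and 1.11 under the other settings, although a knock-in heavy chain might hold that class up, so a lower share beside it stays open. A candidate explanation is that 1 prearranged light chain takes the place of many. The 4 oligos that rose cannot all match it exactly, since 3 of them cover the same framework 2 stretch with different sequences. Whether it matches any of them could not be tested, as the sequence of the knock-in chain is not held here. The rising calls are not stable: with uneven-background spots kept, as first planned, 0 light-chain V oligos rose at 4 months, and with the processed ratios 1 did. With no background subtraction, an offset of 16 or the sample channel alone 4 rose, and with median centring 5. The strain also carries a prearranged heavy chain, whose like effect would be a fall of other heavy-chain V oligos. The heavy-chain or T cell receptor V class showed no such fall at 4 months. Of its 16 oligos, 14 lay above 0, 2 lay below 0 and none was called. The candidate explanation remains a hypothesis, drawn from these data and not tested.

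For the counts within 564 Igi, other splits of the same arrays show whether chance can be excluded. For 12 against 4 months, 2 of 35 splits gave as many oligos as the real one (real 1, highest other 1), so chance cannot be excluded. For 12 against 8 months the real count was 0, which each of the 35 splits reaches whatever the data (highest other 1), so the splits test nothing there. For 8 against 4 months there are 10 splits, too few for a share under 0.05 (real 0, highest other 1). Across the 3 ages, 10 of 100 splits drawn gave as many (real 1, highest other 10), so chance cannot be excluded there either. A split that set the 3 arrays of slide 3 apart gave 6, while the first group of the split with 10 mixes arrays of slides 1 and 2. Counts so far above the real one may come from a structure of the samples other than age, and its source was not tested. With slide as a fixed block the count across the ages was 0.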
